A study of Homo sapiens with 16 samples.

How the data were processed

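RNA from HUVEC and EA.hy926 cells was measured on 16 one-colour HG-U133A arrays, 2 in each of 8 groups. A probe set is a group of short probes for one transcript. Groups and replicate numbers were taken from the sample labels.

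The deposited values were linear intensities, 1 per probe set and array. Their 2% trimmed means lay between 1500.3 and 1500.6 on every array, so the deposited intensity values were taken as already scaled to a common target. The software that summarised the probes, its settings and any background correction are not given in the sources used here. The files held no detection calls, so whether a probe set stood above background on an array is unknown. The experiment files held the array type and no scan or hybridisation batch, so no batch could be modelled. Scaling of this kind sets the average of each array equal, and an array with little labelled RNA can then have raised values for dim probe sets.

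Because the trimmed means lay within 10% of their median, the values were used as deposited, as log2(value + 57.2). The pseudocount was the 10th percentile of all values, and it understates changes of dim probe sets. Left out were 68 control probe sets and 88 probe sets of sex-linked or donor-variable genes. Probe sets under the 40th percentile of the mean log2 value over all arrays, 8851 in number, were left out as dim, and 13276 were tested.

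Gene symbols came from the platform annotation. Of the probe sets, 19065 had 1 symbol, 1043 several and 2107 none. The entrez identifiers of 19059 were found in the RefSeq gene table, and 0 symbols changed. No gene was named from a probe set with several symbols. Among the tested probe sets 11721 had 1 symbol, and they covered 8284 genes, each represented by its brightest probe set in counts of list members. Probe sets of one gene can disagree, and no coordinates are given because no genome was used.

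All comparisons were contrasts of 8 group means in one limma fit (limma 3.58.1, R 4.3.3) over 16 arrays, with 8 residual degrees of freedom and 4.58 added by eBayes. The p-values were adjusted by Benjamini and Hochberg within each comparison, and a probe set was called at an adjusted p under 0.05. An exact permutation test of 2 arrays against 2 cannot go below a two-sided p of 0.333, so single values rest on limma. The fit shares one spread over both cell types, although HUVEC arrays varied more, and a fit within each cell type was an alternative. The comparisons were atorvastatin against untreated, both compounds against atorvastatin, mevalonate against untreated and both compounds against untreated in each cell type, untreated HUVEC against untreated EA.hy926, the difference in the atorvastatin effect between the cell types, and its mean. The overlap of atorvastatin calls was tested with Fisher's exact test, and the share of each atorvastatin change left with mevalonate was taken as a median over the called probe sets. The test of the difference in the mevalonate effect was added after seeing the data. The tests, the samples in each fit, the filters, the gene lists, the rule for naming genes and the alternatives, apart from those said to have been added, were fixed before the data were examined.

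The 29 gene lists of pathways, signalling targets and cell type markers held 535 genes, of which 405 were tested. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way. Lists were adjusted within a comparison.

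Genes were named by a rule. In each comparison they came from called probe sets with 1 symbol in which both arrays of one group lay above both of the other, 1 probe set per gene. The rule as fixed did not say how this applies to contrasts over both cell types. When it was run, the separation was required in at least 1 cell type for a difference between the cell types, and in both for the mean effect. The 10 largest rises and falls were named for atorvastatin against untreated, both compounds against atorvastatin and HUVEC against EA.hy926, and the 5 largest for other comparisons. Up to 4 members of each list with the smallest p were added, called or not. In the statin comparisons 7 further genes were fixed for naming, and 2 of them, which have no probe set named here, are not reported, nor is 1 of the gene lists.

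The fit was tested on simulated data with the real means and the spread of each cell type, in which 200 of 13276 probe sets were changed. For atorvastatin in HUVEC, 11.9%, 65.7% and 87.9% of changes of 2-fold, 4-fold and 8-fold were recovered with all arrays and 29.0% of calls were false. With the HUVEC arrays alone 1.49%, 32.8% and 57.6% were recovered and 6.15% were false. The share of false HUVEC calls with all arrays was thus above the nominal level in this simulation, although its spreads, from 4 degrees of freedom each, overstate how much probe sets differ in spread. For EA.hy926 the recovered shares were 10.4%, 61.2% and 95.5% with all arrays, with 9.02% false, and 11.9%, 65.7% and 90.9% with its own arrays, with 2.61% false. Values for unchanged groups came from 20 simulations, in which every array had the spread shared by both cell types. With the HUVEC arrays alone the counts were 564 in place of 2158 for atorvastatin against untreated and 1005 in place of 2741 for both compounds against atorvastatin.

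The alternatives were quantile normalization, scaling to the same median, a pseudocount 4 times larger or smaller, no filter or a filter at the 60th percentile, a fit within each cell type, eBayes with trend and robust estimation, array weights, the replicate number as a block, and each array left out in turn. For the gene lists the mean of all probe sets of a gene was also tried. The mean log2 of 5' to 3' signal ratios as a covariate, and a fit without the 2 arrays of lowest GAPDH ratio outside HUVEC with atorvastatin, were added after seeing the data. Replicate arrays of a group shared between 2 and 14 identical values, and no array was a copy of another. Figures were drawn with matplotlib 3.10.9.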

Results

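Human endothelial cells were grown with atorvastatin, with mevalonate, with both or with neither, and their RNA was measured on HG-U133A expression arrays of short probes. Atorvastatin is a statin, a drug class that lowers cholesterol by blocking the synthesis of mevalonate. Cells make cholesterol from mevalonate, and also the prenyl chains that anchor small GTPases such as RHOA to membranes. The cells were HUVEC, primary endothelial cells of the umbilical vein, and EA.hy926, an established line made by fusing HUVEC with a lung carcinoma line. Treated cells received 10 µM atorvastatin, 500 µM mevalonate or both for 24 h, and untreated cells were harvested at confluence with no time given. Every comparison with untreated cells may therefore also hold a difference in time or handling. The 16 arrays formed 8 groups, 4 per cell type, with 2 arrays in each group. The labels do not say that the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

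The deposited values were linear intensities scaled to the same 2% trimmed mean on every array, 1500.3 to 1500.6. The median signal lay between 705 and 831 on the 8 HUVEC arrays and between 431 and 484 on the 8 EA.hy926 arrays. The hybridisation control probe sets had a mean signal of 6553 ± 1023 (SD, n = 8) in HUVEC and 1326 ± 508 (SD, n = 8) in EA.hy926, a ratio of 4.94. Within EA.hy926 their signal was 1641 and 2455 on the atorvastatin arrays and between 956 and 1297 in the other groups. Within HUVEC it was 7342 and 7653 on the atorvastatin arrays and between 4497 and 7412 in the other groups. Whether the atorvastatin arrays held less labelled RNA was not tested. Across probe sets, which are not independent replicates, the 2 arrays of a group correlated at a Pearson r of 0.860 to 0.882 in HUVEC and 0.947 to 0.967 in EA.hy926. The pooled SD within groups was 0.54 on the log2 scale in HUVEC and 0.36 in EA.hy926. The number of arrays limits the precision of every value.

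The arrays carry control probe sets at the 5' and 3' ends of the GAPDH and beta-actin transcripts, and a low 5' to 3' signal ratio is a sign of shortened RNA or cDNA. The GAPDH ratio was 0.0234 and 0.0301 on the 2 HUVEC arrays with atorvastatin. It was 0.343 and 0.0973 on untreated HUVEC arrays, 0.447 and 0.440 with both compounds, and 0.557 and 0.622 with mevalonate. In EA.hy926, replicate 1 with atorvastatin had a ratio of 0.0818 and replicate 2 a ratio of 0.655, while the other 6 arrays lay between 0.704 and 1.06. The beta-actin ratio was 0.0630 and 0.0207 in HUVEC with atorvastatin. On untreated HUVEC arrays it was 0.204 for replicate 1 and 0.0393 for replicate 2, so that 1 untreated array lay below 1 of the atorvastatin arrays. In EA.hy926 it was 0.0255 and 0.211 with atorvastatin, and between 0.294 and 0.707 on the other 6 arrays.

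**Figure D1:**
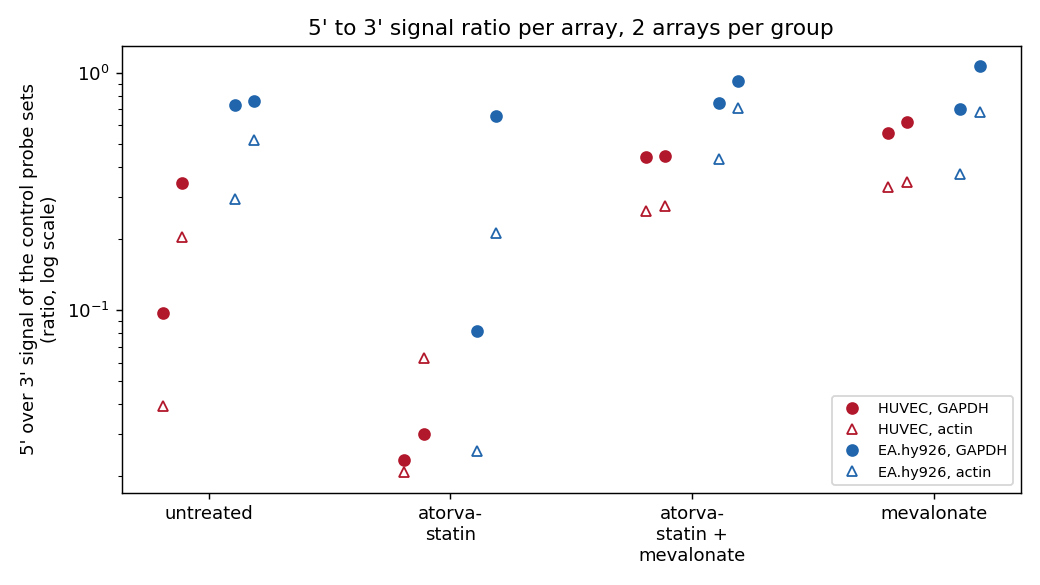
Ratio of 5' to 3' signal (log scale) of the GAPDH (filled circles) and beta-actin (open triangles) control probe sets on each of the 16 arrays, 2 per group, with treatment on the horizontal axis, HUVEC in red and EA.hy926 in blue. The GAPDH ratio of the 2 HUVEC arrays with atorvastatin was 0.0234 and 0.0301, below every other array.

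The first comparison asked what atorvastatin changed in HUVEC. KLF2, a transcription factor that laminar flow induces, was 2.69 ± 0.26 (log2 difference ± SE, n = 2 per group) higher with the drug (limma adjusted p = 0.000113). THBD, which encodes the anticoagulant receptor thrombomodulin, rose by 2.32 ± 0.26 (limma adjusted p = 0.000248), and EDN1, which encodes the vasoconstrictor endothelin 1, changed by -2.37 ± 0.32 (limma adjusted p = 0.000808). The largest falls were the matrix-associated protein CCN2 at -5.15 ± 0.43, IGFBP7 at -4.99 ± 0.37, CCN1 at -4.63 ± 0.34, the tubulin TUBB3 at -4.49 ± 0.34 and thrombospondin 1, THBS1, at -4.37 ± 0.35. RHOB, a small GTPase that carries a prenyl chain, changed by -1.90 ± 0.33 (limma adjusted p = 0.00304), and NOS3, the endothelial nitric oxide synthase, by 0.42 ± 0.45, which did not pass the test (limma adjusted p = 0.549).

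With limma over 13276 probe sets, 607 were higher and 1551 lower with atorvastatin in HUVEC at an adjusted p under 0.05, which covered 407 and 955 genes. An unadjusted p under 0.05 was found for 4336 probe sets, where chance gives 664 if the shared spread holds for HUVEC. The HUVEC arrays varied more than that spread, so chance gives more than 664 here. The other large rises were TRIM10 (3.03 ± 0.42), the protease ADAMTS1 (2.93 ± 0.35), TNFRSF9 (2.84 ± 0.47), thyroglobulin TG (2.81 ± 0.62), CXCR3 (2.77 ± 0.70), KLF4 (2.74 ± 0.53), RHOBTB1 (2.73 ± 0.61), YARS2 (2.71 ± 0.38) and PLS1 (2.66 ± 0.51). The other large falls were DRAP1 (-3.99 ± 0.32), the pattern recognition protein PTX3 (-3.68 ± 0.27), the proteasome subunit PSMA5 (-3.66 ± 0.32), the protease PRSS23 (-3.65 ± 0.28) and the splicing factor PRPF8 (-3.40 ± 0.35). In each of these 20 genes both arrays of one group lay above both of the other, as the rule for naming genes required. All of these comparisons rest on the 2 HUVEC atorvastatin arrays of lowest GAPDH ratio. With the spread estimated from the 8 HUVEC arrays alone, 564 probe sets passed in place of 2158, and TG, CXCR3, KLF4 and RHOBTB1 no longer did. TG, CXCR3 and RHOBTB1 also failed the test without at least 1 single array. The count was 1085 without HUVEC untreated replicate 1 and 1412 without replicate 2. In fits added after seeing the data it was 844 with the mean log2 5' to 3' ratio as a covariate and 1242 without the other 2 arrays of low GAPDH ratio, HUVEC untreated replicate 2 and EA.hy926 atorvastatin replicate 1. With the covariate a median of 96.1% of the change over the calls was left, and of those 20 genes CXCR3, KLF4 and RHOBTB1 did not pass. In simulated HUVEC data of the same size, 45 of 155 calls with all arrays were false, against 4 of 65 with the HUVEC arrays alone.

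With its preset correlation camera called 7 lists in HUVEC. In DNA replication, 12 of 26 measured members were lower and 1 higher (1 and 15 adjusted over the list alone, median -1.06, camera adjusted p = 7.25e-05, adjusted p = 0.0789 with an estimated correlation). Among them were PCNA (-2.22 ± 0.23), MCM2 (-2.57 ± 0.31), CDC6 (-2.31 ± 0.35) and FEN1 (-3.14 ± 0.54). In mitosis, 12 of 30 were lower and 0 higher (0 and 13 adjusted over the list alone, median -0.72, camera adjusted p = 7.45e-05, adjusted p = 0.294 with an estimated correlation). CCNA2 was at -2.67 ± 0.25, AURKB at -2.65 ± 0.37, TOP2A at -2.15 ± 0.33 and PRC1 at -1.79 ± 0.28. Of the heat shock genes, 6 of 10 were lower (0 and 8 adjusted over the list alone, median -1.33, camera adjusted p = 9.59e-05, adjusted p = 0.0789 with an estimated correlation). They included HSPH1 (-1.79 ± 0.27), HSPB1 (-1.66 ± 0.27), HSPE1 (-1.65 ± 0.28) and HSPD1 (-1.22 ± 0.25). Among targets of YAP and TEAD, transcription factors that respond to cell tension, 6 of 15 were lower (0 and 6 adjusted over the list alone, median -0.32, camera adjusted p = 0.00795, adjusted p = 0.124 with an estimated correlation). CRIM1 was at -3.29 ± 0.38 and AXL at -3.19 ± 0.40, besides CCN1 and CCN2. Of the targets of SRF and MRTF, which follow the state of actin, 6 of 18 were lower (0 and 8 adjusted over the list alone, median -1.02, camera adjusted p = 0.00795, adjusted p = 0.313 with an estimated correlation). Among them were FHL2 (-2.45 ± 0.33), beta-actin ACTB (-1.96 ± 0.30), TPM1 (-1.67 ± 0.34) and CALD1 (-1.47 ± 0.31). In extracellular matrix, 8 of 20 were lower and 1 higher (1 and 8 adjusted over the list alone, median -0.63, camera adjusted p = 0.0303, adjusted p = 0.313 with an estimated correlation). LOX was at -2.95 ± 0.36, LAMB1 at -1.66 ± 0.32, LAMC1 at -1.24 ± 0.30 and TGFBI at 2.01 ± 0.45. Of the KLF2 and flow response genes, 4 of 14 were higher and 1 lower (4 and 2 adjusted over the list alone, median 0.50, camera adjusted p = 0.0259, adjusted p = 0.131 with an estimated correlation). ASS1, an enzyme of arginine synthesis, was at 1.32 ± 0.32. None of these 7 calls held with an estimated correlation, and the GAPDH ratio was lower with atorvastatin than without in the same arrays.

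The other 22 lists were not called in HUVEC. In cholesterol synthesis 2 of 15 members were lower, EBP (-2.70 ± 0.51) and SQLE (-1.37 ± 0.42), and none higher (0 and 2 adjusted over the list alone, median -0.23, camera adjusted p = 0.286, adjusted p = 0.618 with an estimated correlation). In the SREBP pathway 1 of 11 was higher, the lipoprotein receptor SCARB1 (1.09 ± 0.27). In fatty acid synthesis 1 of 10 was lower, ACLY (-0.81 ± 0.23), and of the LXR targets 1 of 8 was higher, SMPDL3A (1.35 ± 0.40). Of the prenyl chain enzymes 2 of 12 were lower, RABGGTB (-1.35 ± 0.25) and COQ2 (-1.32 ± 0.39). Of a list of prenylated GTPases 3 of 19 were lower, among them RAB1A (-2.07 ± 0.31) and RHEB (-1.82 ± 0.38). Coagulation had 2 higher, THBD and the plasminogen activator PLAT (1.67 ± 0.28), and 3 lower of 13, with the thrombin receptor F2R at -3.16 ± 0.42. In vascular tone 2 of 15 were higher and 3 lower, with a median of 0.10 and a mean of -0.06. Median and mean also differed in sign for p53 targets (-0.02 and 0.12) and fibroblast and smooth muscle markers (-0.05 and 0.14). None of 15 adhesion molecules and cytokines, 14 p53 targets and 7 blood cell markers passed. Counts of members higher and lower were 1 and 0 of 9 in NF-kB feedback and 3 and 0 of 14 in the interferon response. They were 1 and 4 of 20 in the ATF4 and unfolded protein response, and 0 and 1 of 12 among NRF2 targets. They were 3 and 1 of 19 in angiogenic factors, 2 and 2 of 11 in matrix metalloproteinases and 0 and 3 of 16 in TGF-beta signalling. Cell type markers gave 1 and 2 of 21 endothelial markers, 1 and 1 of 8 epithelial markers and 2 and 1 of 8 fibroblast and smooth muscle markers. Adjusted over the list alone, these 22 lists held 25 higher and 41 lower members, counting a gene once per list.

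The same comparison in EA.hy926 gave 259 calls against 2158 in HUVEC with the spread shared by both cell types, and 584 against 564 with the spread of each cell type's own arrays. PLAT rose by 3.09 ± 0.28 (limma adjusted p = 0.000927, n = 2 per group), THBD by 2.24 ± 0.26 (limma adjusted p = 0.00129) and KLF2 by 1.89 ± 0.26 (limma adjusted p = 0.00414). RHOB rose by 2.87 ± 0.33 (limma adjusted p = 0.00129), in the opposite direction to HUVEC. CCN2 changed by -4.31 ± 0.43, EDN1 by -3.00 ± 0.32 and CCN1 by -2.98 ± 0.34, the largest falls, and NOS3 at 1.43 ± 0.45 did not pass (limma adjusted p = 0.145). The other large rises were DEPP1 (2.80 ± 0.28), PCDH12 (2.80 ± 0.59), the glucocorticoid-induced TSC22D3 (2.62 ± 0.28), KLF9 (2.60 ± 0.43), the integrin ITGB4 (2.60 ± 0.41), ADAMTS1 (2.49 ± 0.35), CLIC3 (2.43 ± 0.40) and S100A4 (2.43 ± 0.42). The other large falls were CDCA8 (-2.96 ± 0.52), the replication licensing factors CDT1 (-2.86 ± 0.63), MCM10 (-2.85 ± 0.45) and MCM2 (-2.70 ± 0.31), DDX31 (-2.78 ± 0.48), RRS1 (-2.72 ± 0.50) and FJX1 (-2.45 ± 0.30).

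With limma, 121 probe sets were higher and 138 lower with atorvastatin in EA.hy926, or 95 and 94 genes, and 1769 had an unadjusted p under 0.05. In simulated EA.hy926 data 11 of 122 calls were false. The count fell from 259 to 34 without atorvastatin replicate 1, the array of low GAPDH ratio, to 131 without replicate 2, and to 27 and 42 without untreated replicate 1 or 2. It was 172 without either array given both compounds and 584 with the spread of the EA.hy926 arrays alone. It was 68 after quantile normalization, 34 with the ratio as a covariate and 29 without the same 2 arrays of low ratio. With the covariate a median of 97.6% of the change was left, with standard errors 1.26 times as large. Of the 20 genes named for size, PLAT, RHOB, DEPP1, TSC22D3, CCN2, EDN1, CCN1, MCM2 and FJX1 stayed past the threshold without any single array, these and ITGB4 passed with the covariate, and PCDH12 did not pass in the fit of the EA.hy926 arrays alone.

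Camera called 10 lists in EA.hy926, of which 6 held with an estimated correlation. In DNA replication 15 of 26 members were lower and none higher (0 and 25 adjusted over the list alone, median -1.65, camera adjusted p = 1.06e-30, adjusted p = 0.000279 with an estimated correlation). Among them were RRM2 (-2.10 ± 0.24), MCM6 (-2.25 ± 0.27) and MCM3 (-2.29 ± 0.33). In mitosis 9 of 30 were lower (0 and 25 adjusted over the list alone, median -1.15, camera adjusted p = 6.45e-24, adjusted p = 0.00611 with an estimated correlation). AURKB was at -2.06 ± 0.37, KIF11 at -1.65 ± 0.31 and CCNB1 at -1.30 ± 0.26. Of the YAP and TEAD targets 4 of 15 were lower (0 and 6 adjusted over the list alone, median -0.87, camera adjusted p = 6.13e-08, adjusted p = 0.00595 with an estimated correlation). These were CCN1, CCN2, FJX1 and DLC1 (-1.29 ± 0.23). In KLF2 and flow response 3 of 14 were higher and none lower (8 and 0 adjusted over the list alone, median 1.16, camera adjusted p = 3.47e-06, adjusted p = 0.00611 with an estimated correlation). KLF2, THBD and TXNIP (1.17 ± 0.25) passed. Of the matrix metalloproteinases and inhibitors 2 of 11 were higher (3 and 0 adjusted over the list alone, median 0.58, camera adjusted p = 0.000667, adjusted p = 0.0215 with an estimated correlation). MMP10 (2.11 ± 0.36) and ADAMTS1 passed. In the list of prenylated GTPases no member of 19 passed, while the list as a whole was higher (0 and 0 adjusted over the list alone, median 0.36, camera adjusted p = 0.00312, adjusted p = 0.0309 with an estimated correlation). The remaining 4 called lists lost their call with an estimated correlation. They included coagulation, endothelial markers and heat shock. Coagulation had 2 higher and 1 lower of 13 (4 and 1 adjusted over the list alone, median 0.40, camera adjusted p = 0.00897, adjusted p = 0.0638 with an estimated correlation). Of the endothelial markers none of 21 passed (1 and 0 adjusted over the list alone, median 0.50, camera adjusted p = 0.0105, adjusted p = 0.222 with an estimated correlation). Heat shock had 1 higher and 2 lower of 10 (1 and 3 adjusted over the list alone, median -0.52, camera adjusted p = 0.0396, adjusted p = 0.180 with an estimated correlation). HSPB1 was at 1.48 ± 0.27, HSPD1 at -1.09 ± 0.25 and HSPE1 at -1.21 ± 0.28. Both atorvastatin arrays behind these lists had a lower GAPDH ratio than the other 6 EA.hy926 arrays, replicate 1 by far the lower.

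Of the other 19 lists, single members passed in vascular tone, where PTGS2, the inducible cyclooxygenase, was at 2.28 ± 0.40 beside EDN1. Others passed in NF-kB feedback (TRAF1, 2.08 ± 0.37), in the ATF4 response (ASNS, -2.01 ± 0.37) and in angiogenic factors (ADAMTS1). FBN1 (1.36 ± 0.26) passed in extracellular matrix and KRT15 (2.26 ± 0.51) among epithelial markers. No member passed in cholesterol synthesis (0 and 0 adjusted over the list alone, median -0.17, camera adjusted p = 0.347, adjusted p = 0.532 with an estimated correlation). The same held for the SREBP pathway (11 measured), fatty acid synthesis (10), LXR targets (8) and prenyl chain enzymes (12). None passed among SRF and MRTF targets (18), adhesion molecules and cytokines (15), the interferon response (14) or p53 targets (14). Nor did any in NRF2 targets (12), TGF-beta signalling (16), fibroblast and smooth muscle markers (8) and blood cell markers (7). Median and mean differed in sign for p53 targets (-0.09 and 0.06) and blood cell markers (0.14 and -0.10). Adjusted over the list alone, these 19 lists held 21 higher and 8 lower members.

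**Figure D2:**
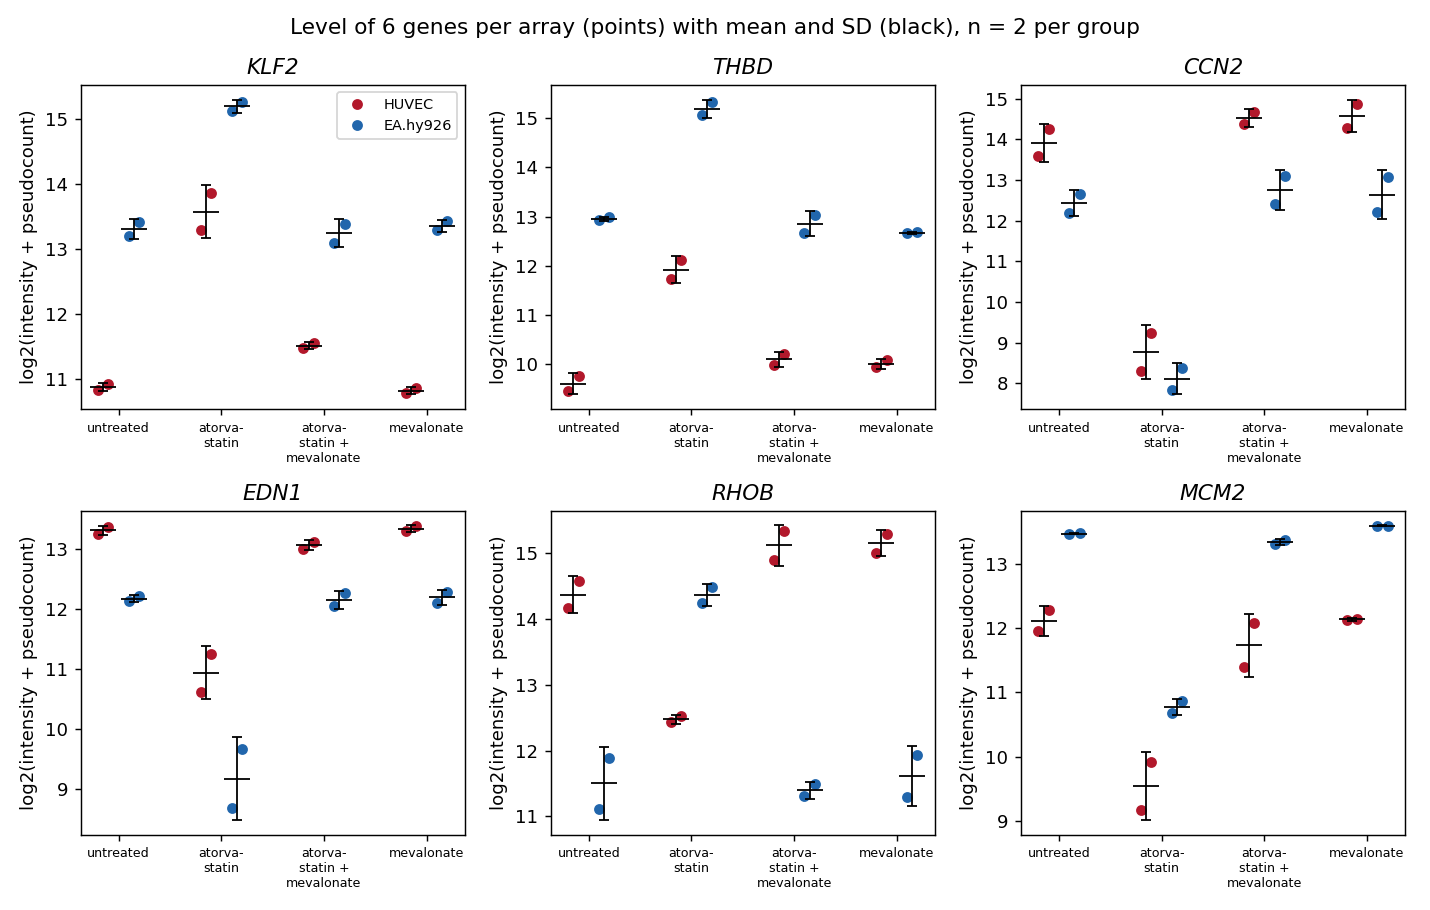
Level of KLF2, THBD, CCN2, EDN1, RHOB and MCM2 as log2(intensity + pseudocount) on the vertical axis against treatment, with each array as a point (HUVEC red, EA.hy926 blue) and the group mean and SD in black, n = 2 per group. RHOB was -1.90 in HUVEC and 2.87 in EA.hy926 with atorvastatin against untreated, while CCN2 fell in both, -5.15 and -4.31.

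The responses of the 2 cell types were then compared. The effect on RHOB was lower in HUVEC than in EA.hy926 by the largest margin, -4.76 ± 0.47 (HUVEC effect minus EA.hy926 effect, log2 ± SE, limma adjusted p = 0.00127). It was followed by IGFBP7 (-4.61 ± 0.53), RESF1 (-3.91 ± 0.73), DEPP1 (-3.88 ± 0.40) and CD9 (-3.67 ± 0.72). The largest differences the other way were in DDX31 (3.87 ± 0.68), the DNA repair gene RAD54L (3.84 ± 0.71), EPX (3.66 ± 0.84), GTF3C5 (3.55 ± 0.85) and RNFT2 (3.48 ± 0.34). HSPB1 (-3.14 ± 0.38) fell in HUVEC and rose in EA.hy926, and ASNS (3.22 ± 0.52), which makes asparagine, rose in HUVEC and fell in EA.hy926. The difference did not pass the test for KLF2 at 0.81 ± 0.37 (limma adjusted p = 0.235) or THBD at 0.08 ± 0.37 (limma adjusted p = 0.925). Nor did it for EDN1 at 0.63 ± 0.46 (limma adjusted p = 0.469) or NOS3 at -1.01 ± 0.63 (limma adjusted p = 0.394).

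In all, 122 probe sets had a higher and 406 a lower atorvastatin effect in HUVEC than in EA.hy926 by limma, 74 and 260 genes. Without EA.hy926 untreated replicate 1 or 2 this count of 528 was 47 or 40, without EA.hy926 atorvastatin replicate 1 or 2 it was 122 or 201, and without HUVEC untreated replicate 1 or 2 it was 175 or 311. It was 350 without either EA.hy926 mevalonate array and 304 without either EA.hy926 array given both compounds. It was 109 without HUVEC untreated replicate 2 and EA.hy926 atorvastatin replicate 1 together. RNFT2, RHOB, IGFBP7 and DEPP1 passed without any single array. Camera called 7 lists, none of which held with an estimated correlation. The list of prenylated GTPases had 2 of 19 lower (0 and 2 adjusted over the list alone, median -0.73, camera adjusted p = 0.00412, adjusted p = 0.0993 with an estimated correlation) and coagulation 3 of 13 (0 and 6 adjusted over the list alone, median -1.01, camera adjusted p = 0.00508, adjusted p = 0.0993 with an estimated correlation). Extracellular matrix had 2 of 20 lower (1 and 7 adjusted over the list alone, median -0.82, camera adjusted p = 0.00412, adjusted p = 0.296 with an estimated correlation) and heat shock 2 of 10 (0 and 2 adjusted over the list alone, median -0.59, camera adjusted p = 0.0487, adjusted p = 0.296 with an estimated correlation). Endothelial markers had 1 higher and 1 lower of 21 (1 and 5 adjusted over the list alone, median -0.73, camera adjusted p = 0.0369, adjusted p = 0.509 with an estimated correlation). The median of DNA replication fell in both cell types and by less in HUVEC, -1.06 against -1.65 in EA.hy926. The difference was positive and called for 2 of 26 members (4 and 0 adjusted over the list alone, median 0.68, camera adjusted p = 0.000719, adjusted p = 0.0993 with an estimated correlation). The members that passed included RAB1A (-2.40 ± 0.43), RHEB (-2.23 ± 0.54), TFPI (-2.23 ± 0.39), LOX (-2.48 ± 0.50), COL18A1 (-2.00 ± 0.46), E2F1 (2.21 ± 0.40) and GINS2 (2.29 ± 0.55).

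The atorvastatin calls of the 2 cell types overlapped. Among probe sets called in each, 21 were higher in both and 54 lower in both, where independent lists would share 5.53 and 16.1 (Fisher's exact test, two-sided, across probe sets, p = 1.20e-07 and p = 8.73e-17). Opposite directions were found for 12, where independent lists give 20.4. The changes correlated across all tested probe sets at a Pearson r of 0.216 and a Spearman correlation of 0.194, and probe sets are not independent replicates. The 75 shared probe sets included KLF2, THBD, PLAT, ADAMTS1, ITGB4 and TSC22D3 among the rises, and CCN1, CCN2, THBS1, EDN1, PCNA, TOP2A, CDC6, MCM2, MCM3 and MCM6 among the falls. Their number was 17 and 43 without EA.hy926 atorvastatin replicate 1 or 2, 11 and 17 without EA.hy926 untreated replicate 1 or 2, and 44 without either EA.hy926 array given both compounds. It was 14 with the ratio as a covariate, 26 with quantile normalization, 31 with no filter, 32 with the replicate block and 124 with trend and robust estimation. Independent lists would share 1.32, 7.86, 6.13, 7.60 and 36.9 in these fits, against 21.7 in the main fit. A lower shared count there thus goes with fewer calls and is not by itself a weaker overlap. The Pearson r, which does not depend on calls, was 0.135 without EA.hy926 atorvastatin replicate 1 and 0.244 without replicate 2. It was 0.131 without HUVEC untreated replicate 2 and EA.hy926 atorvastatin replicate 1 together, and 0.244 with the covariate. The correlation was thus weaker without the EA.hy926 array of low GAPDH ratio.

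The mean atorvastatin effect over both cell types was largest for CCN2 (-4.73 ± 0.30, limma adjusted p = 8.57e-06), CCN1 (-3.81 ± 0.24), THBS1 (-3.20 ± 0.25), TUBB3 (-2.82 ± 0.24) and EDN1 (-2.68 ± 0.23) among the falls. The largest rises were ADAMTS1 (2.71 ± 0.24), ITGB4 (2.61 ± 0.29), PCDH12 (2.49 ± 0.42), PLAT (2.38 ± 0.20) and KLF4 (2.36 ± 0.38). KLF2 rose by 2.29 ± 0.18 and THBD by 2.28 ± 0.18, while NOS3 at 0.93 ± 0.32 (limma adjusted p = 0.0758) and RHOB at 0.48 ± 0.23 (limma adjusted p = 0.195) did not pass. By limma 431 probe sets were higher and 1106 lower on average, 290 and 681 genes. The total of 1537 was 683 without EA.hy926 atorvastatin replicate 1, 663 and 756 without EA.hy926 untreated replicate 1 or 2, and 945 without HUVEC untreated replicate 1. With the ratio as a covariate it was 98, a median of 90.6% of the change was left with standard errors 1.46 times as large, and of the 5 largest rises and falls PCDH12 and KLF4 did not pass. It was 526 without HUVEC untreated replicate 2 and EA.hy926 atorvastatin replicate 1. DNA replication had 19 of 26 members lower (0 and 23 adjusted over the list alone, median -1.43, camera adjusted p = 3.56e-17, adjusted p = 0.00237 with an estimated correlation). Mitosis had 19 of 30 lower (0 and 25 adjusted over the list alone, median -0.96, camera adjusted p = 1.63e-15, adjusted p = 0.0234 with an estimated correlation) and YAP and TEAD targets 7 of 15 (0 and 8 adjusted over the list alone, median -0.72, camera adjusted p = 4.49e-06, adjusted p = 0.0148 with an estimated correlation). Heat shock had 6 of 10 lower (0 and 6 adjusted over the list alone, median -0.85, camera adjusted p = 7.39e-05, adjusted p = 0.0318 with an estimated correlation). KLF2 and flow response had 6 of 14 members higher (8 and 1 adjusted over the list alone, median 0.85, camera adjusted p = 0.000129, adjusted p = 0.0191 with an estimated correlation). SRF and MRTF targets had 4 of 18 lower (0 and 6 adjusted over the list alone, median -0.43, camera adjusted p = 0.0147, adjusted p = 0.287 with an estimated correlation). Angiogenic factors had 4 higher and 1 lower of 19 (6 and 2 adjusted over the list alone, median 0.33, camera adjusted p = 0.0460, adjusted p = 0.119 with an estimated correlation). These last 2 lists lost their call with an estimated correlation.

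**Figure D3:**
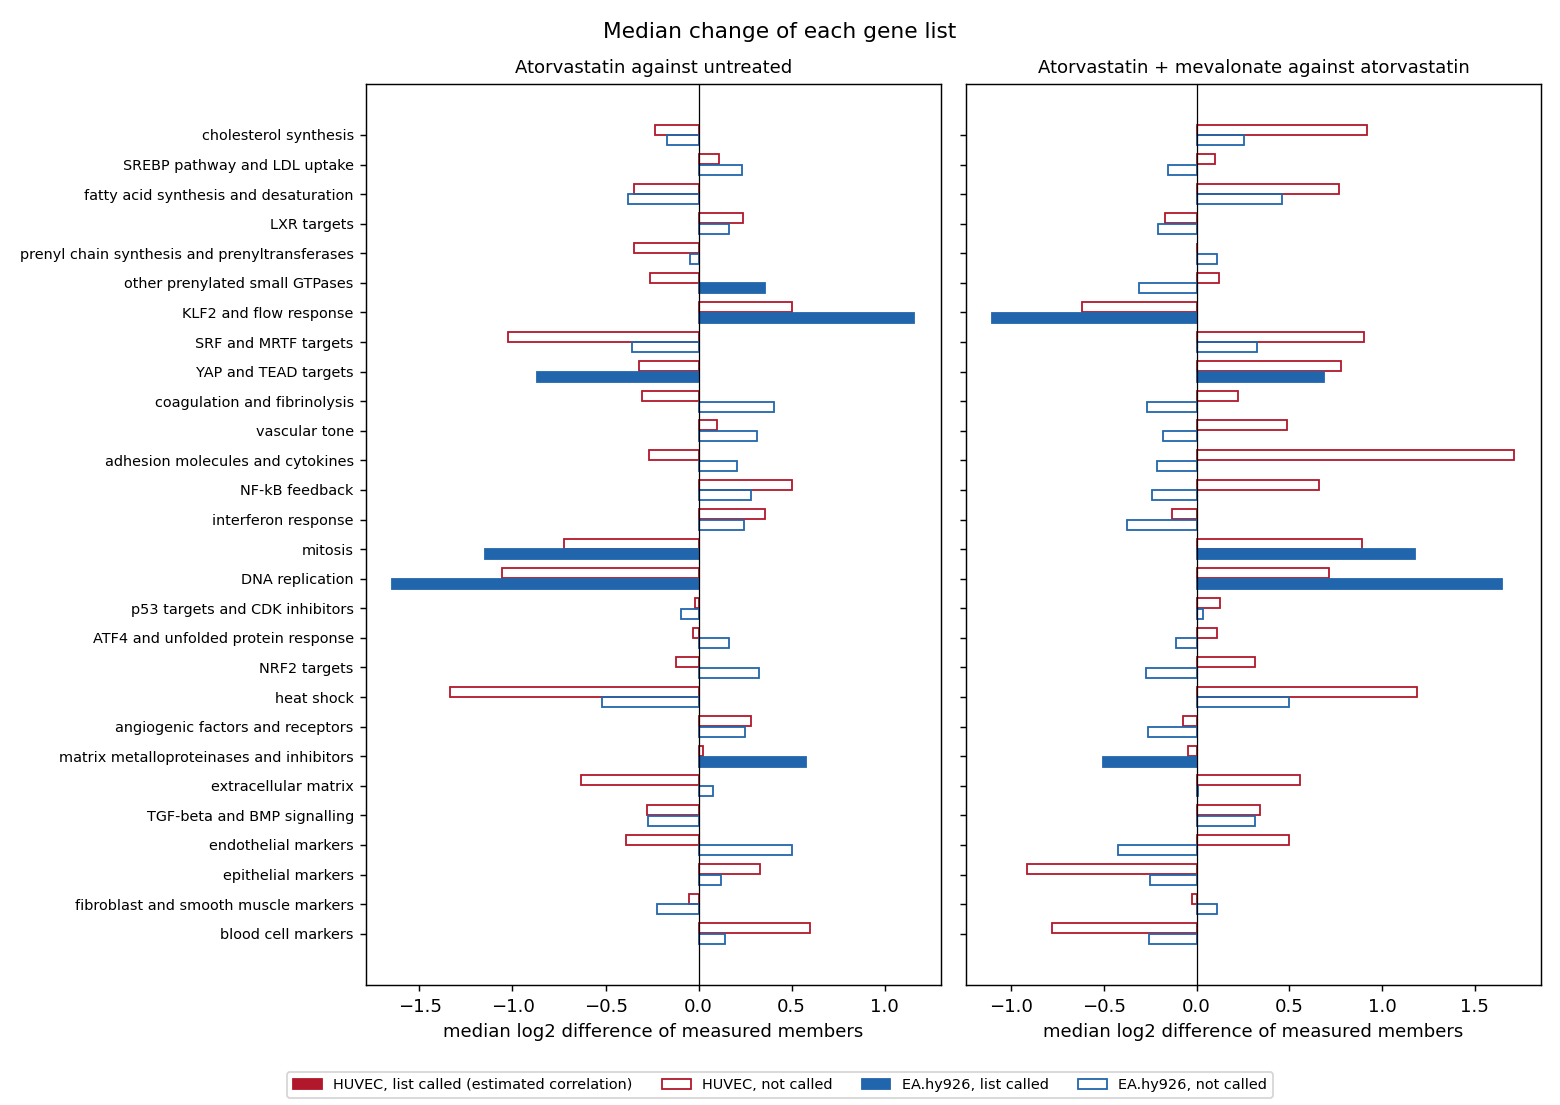
Median log2 difference of the measured members of each of 28 gene lists (horizontal bars, HUVEC red, EA.hy926 blue), for atorvastatin against untreated on the left and atorvastatin plus mevalonate against atorvastatin on the right, with filled bars where camera with an estimated correlation called the list. DNA replication in EA.hy926 had a median of -1.65 with atorvastatin and 1.65 when mevalonate was added to it.

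Mevalonate added with atorvastatin was compared with atorvastatin alone, to ask which statin effects the supply of mevalonate removes. In HUVEC the strongest rises were in cytokines and in genes that atorvastatin had lowered. CXCL2 was at 6.60 ± 0.60 (log2 ± SE, n = 2 per group, limma adjusted p = 4.77e-05), CCN2 at 5.76 ± 0.43, CXCL8 at 5.60 ± 0.38, IGFBP7 at 5.34 ± 0.37 and CXCL1 at 5.10 ± 0.38. THBS1 was at 4.82 ± 0.35, CCN1 at 4.70 ± 0.34, TUBB3 at 4.52 ± 0.34, the adhesion molecule SELE at 4.47 ± 0.42 and CCL2 at 4.34 ± 0.69. KLF2 changed by -2.06 ± 0.26 (limma adjusted p = 0.000345), THBD by -1.82 ± 0.26 and EDN1 by 2.13 ± 0.32. RHOB changed by 2.64 ± 0.33 (limma adjusted p = 0.000329), while NOS3 at 0.49 ± 0.45 did not pass (limma adjusted p = 0.461). The largest falls were DAGLA (-3.53 ± 0.28), NMNAT2 (-3.04 ± 0.29), KLF4 (-3.02 ± 0.53), WDR5B (-3.02 ± 0.47), NSD3 (-2.95 ± 0.44), BICRAL (-2.85 ± 0.28), ALPG (-2.76 ± 0.51), SGTA (-2.66 ± 0.59), ITGB4 (-2.48 ± 0.41) and PKP3 (-2.45 ± 0.62).

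In HUVEC 1821 probe sets were higher and 920 lower by limma with both compounds than with atorvastatin, 1100 and 598 genes. The count of 2741 was 1005 with the spread of the HUVEC arrays alone, where SGTA and PKP3 did not pass (nor did they without at least 1 single array), and 1397 without HUVEC replicate 1 given both compounds. The GAPDH ratio was higher with both compounds than with atorvastatin alone, and the count was 146 with the mean log2 ratio as a covariate. There a median of 87.5% of the change over the 2741 calls was left and standard errors were 1.62 times as large. Of the 20 genes named for size CCL2, KLF4, WDR5B, NSD3, ALPG, SGTA and PKP3 did not pass with the covariate. The share of calls that were higher was 66.4% with the deposited scaling and 78.1% (2034 higher and 571 lower) with arrays scaled to the same median, which moved the median of all tested probe sets from -0.02 to 0.11. Relative to those medians, the list medians with the deposited and the same-median scaling were 0.94 and 0.94 for cholesterol synthesis and 1.74 and 1.72 for adhesion molecules and cytokines.

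Cholesterol synthesis had 7 of 15 members higher and none lower in HUVEC (8 and 0 adjusted over the list alone, median 0.92, camera adjusted p = 0.00144, adjusted p = 0.169 with an estimated correlation). Among them were EBP (3.94 ± 0.51), SQLE (2.46 ± 0.42), ACAT2 (1.43 ± 0.30) and IDI1 (1.13 ± 0.25). Fatty acid synthesis had 3 of 10 higher (5 and 0 adjusted over the list alone, median 0.77, camera adjusted p = 0.0282, adjusted p = 0.148 with an estimated correlation). These were ACLY (1.12 ± 0.23), SCD (1.35 ± 0.33) and FADS2 (0.89 ± 0.28). Of the adhesion molecules and cytokines 9 of 15 were higher (9 and 0 adjusted over the list alone, median 1.71, camera adjusted p = 0.000161, adjusted p = 0.140 with an estimated correlation). DNA replication had 9 of 26 members higher and 1 lower (10 and 1 adjusted over the list alone, median 0.72, camera adjusted p = 0.00144, adjusted p = 0.148 with an estimated correlation). Mitosis had 12 of 30 higher (17 and 0 adjusted over the list alone, median 0.89, camera adjusted p = 0.000203, adjusted p = 0.256 with an estimated correlation). Among the cell division genes were CCNA2 (3.15 ± 0.25), AURKB (3.16 ± 0.37) and PCNA (2.31 ± 0.23). Heat shock had 7 of 10 members higher (7 and 0 adjusted over the list alone, median 1.19, camera adjusted p = 0.000686, adjusted p = 0.140 with an estimated correlation). YAP and TEAD targets had 6 of 15 higher (7 and 2 adjusted over the list alone, median 0.78, camera adjusted p = 0.0219, adjusted p = 0.148 with an estimated correlation). SRF and MRTF targets had 6 higher and 1 lower of 18 (9 and 2 adjusted over the list alone, median 0.90, camera adjusted p = 0.0264, adjusted p = 0.351 with an estimated correlation). Extracellular matrix had 8 higher and 1 lower of 20 (8 and 1 adjusted over the list alone, median 0.56, camera adjusted p = 0.0219, adjusted p = 0.317 with an estimated correlation). None of these 9 calls held with an estimated correlation. KLF2 and flow response was not called, with 2 higher and 4 lower of 14 (2 and 5 adjusted over the list alone, median -0.62, camera adjusted p = 0.191, adjusted p = 0.317 with an estimated correlation).

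In EA.hy926 the same comparison raised CCN2 (4.64 ± 0.43, limma adjusted p = 0.00106), CDCA8 (3.36 ± 0.52), CCN1 (3.05 ± 0.34), MYC (3.01 ± 0.71), EDN1 (2.98 ± 0.32) and CCL2 (2.91 ± 0.69). Also higher were MCM10 (2.69 ± 0.45), RRS1 (2.57 ± 0.50), MCM2 (2.57 ± 0.31) and FJX1 (2.51 ± 0.30). It lowered PCDH12 (-3.32 ± 0.59), RHOB (-2.97 ± 0.33), PLAT (-2.87 ± 0.28), MMP10 (-2.81 ± 0.36), TSC22D3 (-2.76 ± 0.28), PTGDS (-2.63 ± 0.55), DEPP1 (-2.57 ± 0.28), PTGS2 (-2.51 ± 0.40), PDLIM4 (-2.48 ± 0.37) and ADAMTS1 (-2.47 ± 0.35). THBD changed by -2.34 ± 0.26 and KLF2 by -1.95 ± 0.26, and NOS3 at -1.19 ± 0.45 did not pass (limma adjusted p = 0.199). By limma 177 probe sets were higher and 142 lower, 115 and 107 genes. The total of 319 was 50 and 143 without atorvastatin replicate 1 or 2 and 21 and 69 without replicate 1 or 2 given both compounds. It was 193 without either untreated array and 766 with the spread of the EA.hy926 arrays alone. Atorvastatin replicate 1 had the low GAPDH ratio, and the total was 14 with the ratio as a covariate, where a median of 93.2% of the change was left and standard errors were 1.32 times as large. Of the 20 genes named for size, CCN2, CCN1, EDN1, MCM2, FJX1, RHOB, PLAT, TSC22D3 and DEPP1 passed without any single array and the other 11 did not. Of those 9, MCM2 and FJX1 did not pass with the covariate.

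Among the lists in EA.hy926, DNA replication had 15 of 26 members higher (25 and 0 adjusted over the list alone, median 1.65, camera adjusted p = 4.19e-28, adjusted p = 0.000389 with an estimated correlation). Mitosis had 14 of 30 higher (24 and 0 adjusted over the list alone, median 1.18, camera adjusted p = 7.77e-23, adjusted p = 0.00710 with an estimated correlation). YAP and TEAD targets had 6 of 15 higher (7 and 0 adjusted over the list alone, median 0.69, camera adjusted p = 2.62e-09, adjusted p = 0.00339 with an estimated correlation). KLF2 and flow response had 3 of 14 members lower (0 and 9 adjusted over the list alone, median -1.10, camera adjusted p = 8.05e-06, adjusted p = 0.00710 with an estimated correlation). Matrix metalloproteinases had 2 of 11 lower (0 and 3 adjusted over the list alone, median -0.50, camera adjusted p = 0.000647, adjusted p = 0.0212 with an estimated correlation). Coagulation had 1 higher and 2 lower of 13 (1 and 4 adjusted over the list alone, median -0.27, camera adjusted p = 0.0421, adjusted p = 0.128 with an estimated correlation). Coagulation lost its call with an estimated correlation, and all of these lists include the atorvastatin array of low GAPDH ratio.

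Over the 2158 probe sets that atorvastatin changed in HUVEC, a median of 5.41% of the change was left when mevalonate was added (-2.18% and 13.1% in the 2 arrays), and 1922 (89.1%) kept under 50% of it. Of these probe sets 1561 were called in the return direction and 8 still differed from untreated cells. The GAPDH ratio returned on the same arrays, from 0.0234 and 0.0301 with atorvastatin to 0.447 and 0.440 with both compounds. With the ratio as a covariate the share left was 2.55% over the calls of that fit. In EA.hy926 a median of 1.11% of the change was left over 259 probe sets, and 98.1% kept under 50%. Of them 216 were called in the return direction and 0 still differed from untreated cells. For both compounds against untreated cells limma gave an unadjusted p under 0.05 for 144 of all tested probe sets, where chance gives 664. The shared spread is wider than that of the EA.hy926 arrays, so the 0 does not show a full return. In EA.hy926 the GAPDH ratio was 0.0818 and 0.655 with atorvastatin and 0.922 and 0.743 with both compounds, and the share left with the covariate was 3.57%. Without single arrays the share left ranged from -3.26% to 15.0% in HUVEC and from -1.06% to 8.15% in EA.hy926, where it was 5.97% and 8.15% without untreated replicate 1 or 2. In simulations where mevalonate changed nothing, 92.0% of the change was left in HUVEC and 88.0% in EA.hy926, with 0 called back in limma fits. In HUVEC with both compounds against untreated cells, KLF2 was at 0.63 ± 0.26 (limma adjusted p = 0.478), THBD at 0.49 ± 0.26, EDN1 at -0.24 ± 0.32, RHOB at 0.75 ± 0.33 and NOS3 at 0.91 ± 0.45, none of which passed.

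The last treatment comparison asked what mevalonate did to cells without the drug. In HUVEC cytokine and adhesion genes were higher with mevalonate than in untreated cells, for which no time was given. A difference in time between these groups cannot be told apart from mevalonate. CXCL2 rose by 6.06 ± 0.60 (limma adjusted p = 0.000900), from a signal of 295 ± 269.9 to 19653 ± 1569 (SD, n = 2). CCL2 rose by 4.96 ± 0.69 (limma adjusted p = 0.00811), CXCL8 by 4.77 ± 0.38 (limma adjusted p = 0.000172), CXCL1 by 4.60 ± 0.38 and the leukocyte adhesion receptor SELE by 4.02 ± 0.42. NFKBIA, an inhibitor that NF-kB itself induces, rose by 2.75 ± 0.39 (limma adjusted p = 0.0103). Of the adhesion molecules and cytokines 7 of 15 were higher (9 and 0 adjusted over the list alone, median 2.13, camera adjusted p = 1.65e-16, adjusted p = 0.00504 with an estimated correlation). NF-kB feedback had 1 of 9 higher (5 and 0 adjusted over the list alone, median 0.79, camera adjusted p = 1.67e-07, adjusted p = 0.00504 with an estimated correlation). The largest falls were SPEF1 (-2.02 ± 0.33), MAGEH1 (-1.92 ± 0.30), FCAR (-1.88 ± 0.33), MUC1 (-1.82 ± 0.31) and ERN2 (-1.79 ± 0.33). By limma 31 probe sets were higher and 9 lower, 19 and 6 genes. With the spread of the HUVEC arrays alone 4 passed in place of 40; of the named genes CXCL8, CXCL1 and SELE still did and CXCL2, CCL2 and the 5 falls did not. Each of the 5 falls also failed the test without at least 1 single array. The count was 24 without either EA.hy926 mevalonate array. The GAPDH ratio was higher with mevalonate than in untreated HUVEC, and the count was 15 with the ratio as a covariate, where a median of 99.0% of the change was left and, of the 5 largest rises and falls, CCL2 and the 5 falls did not pass.

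These genes were also higher in HUVEC given both compounds than in untreated HUVEC. CXCL2 was at 5.92 ± 0.60 (limma adjusted p = 0.000937), CXCL8 at 4.50 ± 0.38, SELE at 4.20 ± 0.42, CCL2 at 4.17 ± 0.69, CXCL1 at 4.13 ± 0.38 and NFKBIA at 2.15 ± 0.39. The largest falls were BICRAL (-2.32 ± 0.28), DAGLA (-2.17 ± 0.28), MAGEA6 (-2.06 ± 0.30), BTN1A1 (-1.93 ± 0.33) and ZNF804A (-1.80 ± 0.27). Adhesion molecules and cytokines had 7 of 15 higher (9 and 0 adjusted over the list alone, median 1.76, camera adjusted p = 1.72e-15, adjusted p = 0.00727 with an estimated correlation). NF-kB feedback had 1 of 9 higher (3 and 0 adjusted over the list alone, median 0.61, camera adjusted p = 9.88e-06, adjusted p = 0.0124 with an estimated correlation). No member of cholesterol synthesis passed (0 and 0 adjusted over the list alone, median 0.53, camera adjusted p = 9.96e-06, adjusted p = 0.0932 with an estimated correlation). Nor did any of fatty acid synthesis (0 and 0 adjusted over the list alone, median 0.33, camera adjusted p = 0.0242, adjusted p = 0.112 with an estimated correlation). These 2 lists lost their call with an estimated correlation. Limma called 24 probe sets higher and 8 lower, 17 and 6 genes. It called 3 in place of 32 with the spread of the HUVEC arrays alone, where CXCL8, SELE and CXCL1 passed and CXCL2, CCL2 and the 5 falls did not. CCL2 and the falls other than BICRAL also failed the test without at least 1 single array. The count was 88 without HUVEC replicate 1 given both compounds, 57 without either HUVEC atorvastatin array, and 17 and 21 without HUVEC untreated replicate 1 or 2. It was 15, 16 or 17 without 1 of the EA.hy926 arrays given mevalonate, nothing or both compounds. The GAPDH ratio was again higher than in untreated HUVEC, and the count was 13 with the ratio as a covariate and 9 without the 2 arrays of low ratio. With the covariate a median of 101% of the change was left, and of the 5 largest rises and falls CCL2, MAGEA6, BTN1A1 and ZNF804A did not pass. The 2 comparisons with untreated HUVEC shared 17 calls, where simulated unchanged groups against the same controls shared 0 by limma and independent lists would share 0.0615. Their changes had a covariance of 0.187, against 0.0905 in the simulation, a difference of 0.0962. Their Pearson r across probe sets was 0.599, against 0.50 in the simulation, and with only 2 untreated arrays part of the excess may come from the shared controls. The simulation drew every array with the spread shared by both cell types, although HUVEC arrays varied more. Its covariance is therefore too low a reference for HUVEC, and how much of the difference is real cannot be read from it. In EA.hy926, where arrays varied less, the same pair had a covariance of 0.0381, against 0.0902 in the simulation.

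In EA.hy926 limma called 0 probe sets for mevalonate against untreated cells and 0 for both compounds against untreated cells. An unadjusted p under 0.05 was found for 117 and 144, where chance gives 664. The shared spread is wider than that of the EA.hy926 arrays, so these p-values are too large and 0 calls do not show that nothing changed. No gene list was called in either comparison. Without EA.hy926 mevalonate replicate 1 the first count was 1, and without EA.hy926 replicate 2 given both compounds the other was 1. The difference in the mevalonate effect between the cell types, a test chosen after seeing the data, was called for 6 probe sets with a higher and 2 with a lower effect in HUVEC by limma. CXCL2 differed by 5.69 ± 0.85 (limma adjusted p = 0.0443), CXCL8 by 5.30 ± 0.54 (limma adjusted p = 0.00419), CXCL1 by 4.44 ± 0.54, SELE by 4.43 ± 0.59, GTF2B by 2.53 ± 0.39 and AQP6 by -3.04 ± 0.40. Adhesion molecules and cytokines had 4 of 15 higher (8 and 0 adjusted over the list alone, median 1.72, camera adjusted p = 2.04e-16, adjusted p = 0.00596 with an estimated correlation). In NF-kB feedback none of 9 passed while the list was called (1 and 0 adjusted over the list alone, median 0.64, camera adjusted p = 0.000322, adjusted p = 0.0327 with an estimated correlation). Leaving out single arrays gave counts from 0 to 12 in place of 8, and at most 5 where the array left out was not one of HUVEC with atorvastatin. Each of the 6 genes failed the test in at least 1 of those fits.

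**Figure D4:**
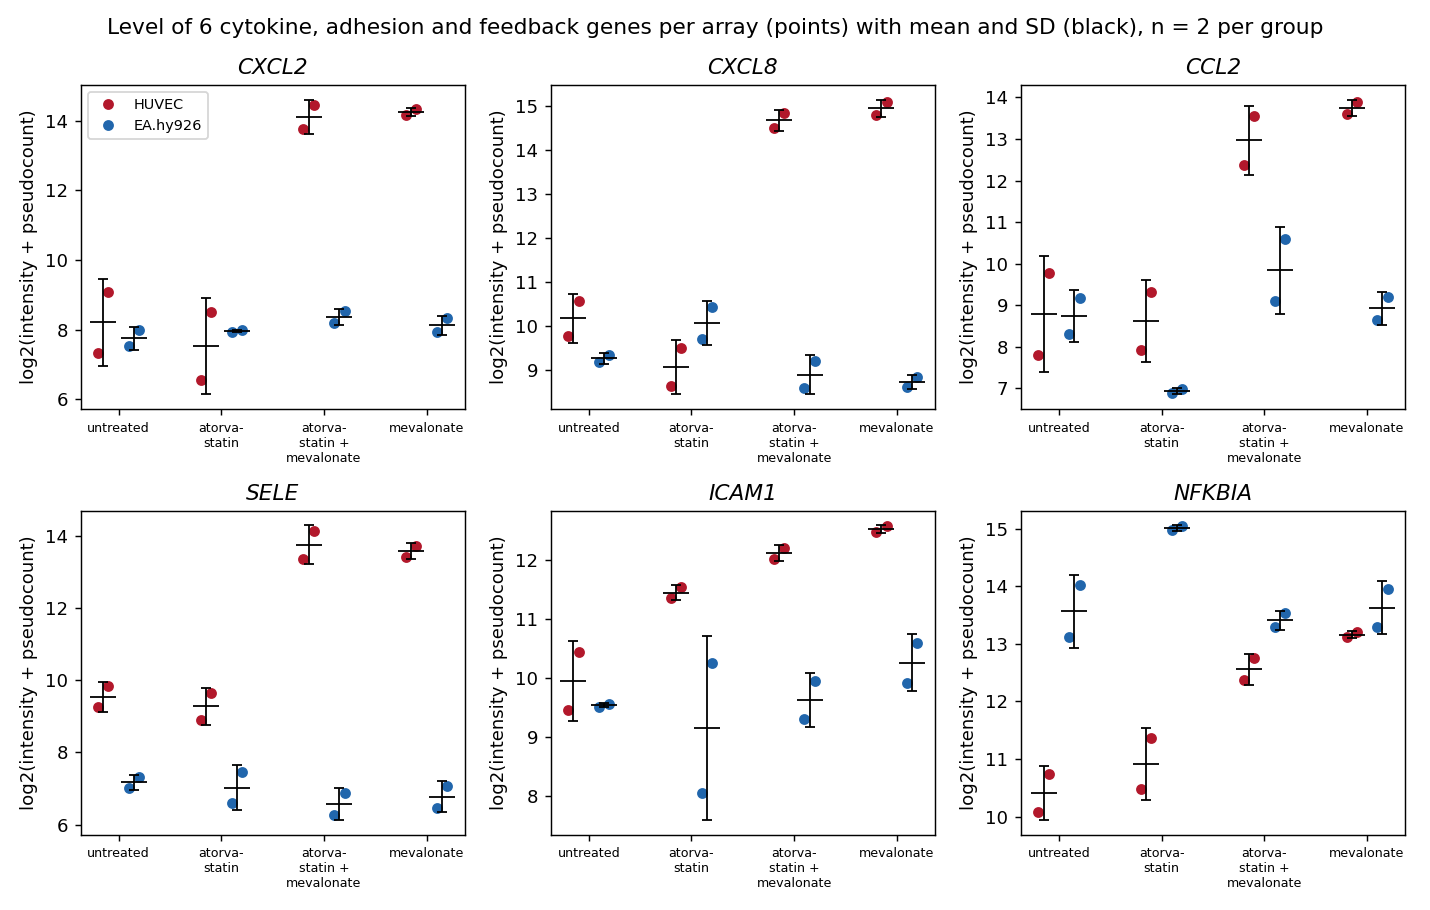
Level of CXCL2, CXCL8, CCL2, SELE, ICAM1 and NFKBIA as log2(intensity + pseudocount) on the vertical axis against treatment, with each array as a point (HUVEC red, EA.hy926 blue) and the group mean and SD in black, n = 2 per group. In HUVEC, CXCL2 was 6.06 higher with mevalonate and 5.92 higher with both compounds than in untreated cells.

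Untreated HUVEC and EA.hy926 differed widely, and values are given as HUVEC minus EA.hy926, so that a negative value was higher in EA.hy926. HUVEC had more of the endothelial genes VWF (7.31 ± 0.51, log2 ± SE, limma adjusted p = 2.49e-06), the tight junction gene CLDN5 (6.05 ± 0.31), the VEGF receptors FLT1 (3.29 ± 0.34) and KDR (2.99 ± 0.41) and MMRN1 (4.82 ± 0.46). Also higher were MGP (6.91 ± 0.36), NES (6.59 ± 0.32), LDB2 (5.89 ± 0.40), ALDH2 (5.61 ± 0.49), BTNL8 (5.42 ± 0.40), RNF144A (5.24 ± 0.28), PPP1R16B (5.15 ± 0.35) and GIPC2 (5.13 ± 0.39). EA.hy926 had more of the epithelial keratins KRT7 (-6.07 ± 0.56), KRT8 (-5.07 ± 0.33) and KRT18 (-3.05 ± 0.26). It also had more TGFBI (-6.90 ± 0.45), CRIP1 (-6.16 ± 0.26), CST1 (-5.87 ± 0.50), EHBP1L1 (-4.74 ± 0.46), PLCB4 (-4.63 ± 0.47), COPE (-4.56 ± 0.87), TNNT1 (-4.25 ± 0.60) and TMEM158 (-4.22 ± 0.53). All 20 genes named for size passed without any single array.

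By limma 3685 probe sets were higher and 2424 lower in HUVEC, 2430 and 1530 genes, and the total of 6109 was 3923 without EA.hy926 untreated replicate 2. The share of calls that were higher in HUVEC was 60.3%, and 49.7% (2577 and 2603) after quantile normalization and 26.3% (1873 and 5253) with arrays scaled to the same median. The median of all tested probe sets was 0.16, -0.05 and -0.61 under these scalings, so list medians are given relative to it, in that order. Endothelial markers, 13 higher and 1 lower of 21 (13 and 1 adjusted over the list alone, median 1.47, camera adjusted p = 0.00118, adjusted p = 0.262 with an estimated correlation), lay at 1.32, 1.33 and 1.34. Adhesion molecules and cytokines, 9 of 15 higher (11 and 0 adjusted over the list alone, median 1.40, camera adjusted p = 0.00610, adjusted p = 0.262 with an estimated correlation), lay at 1.24, 0.72 and 1.31. DNA replication, 16 of 26 lower (0 and 17 adjusted over the list alone, median -1.26, camera adjusted p = 1.13e-05, adjusted p = 0.0854 with an estimated correlation), lay at -1.41, -0.99 and -1.41. Mitosis, 9 of 30 lower (0 and 7 adjusted over the list alone, median -0.68, camera adjusted p = 0.00148, adjusted p = 0.307 with an estimated correlation), lay at -0.84, -0.51 and -0.85. Heat shock, 5 of 10 lower (0 and 5 adjusted over the list alone, median -0.73, camera adjusted p = 0.00708, adjusted p = 0.262 with an estimated correlation), lay at -0.88, -0.27 and -0.90. None of these 5 calls held with an estimated correlation. Lists that were not called included vascular tone, 9 higher and 1 lower of 15, and extracellular matrix, 12 and 3 of 20. The counts were 3 and 4 of 8 for epithelial markers, 6 and 1 of 8 for fibroblast and smooth muscle markers and 6 and 0 of 7 for blood cell markers. Adjusted over the list alone these 5 lists had, in that order, 9 and 1, 13 and 4, 3 and 5, 6 and 2, and 6 and 0. KLF2 (-2.43 ± 0.26), THBD (-3.35 ± 0.26), NOS3 (-3.11 ± 0.45) and NFKBIA (-3.15 ± 0.39) were lower in untreated HUVEC than in EA.hy926, and RHOB (2.88 ± 0.33) was higher.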

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

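The tests of a linear trend with the 5' to 3' ratio, of low untreated values, of blood cells and of the mevalonate preparation, the difference in the mevalonate effect itself, and the GAPDH values without single arrays, were chosen after the result was seen.

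The effect of atorvastatin differed between the cell types, by a test of the difference in limma, for 528 probe sets. The difference, HUVEC minus EA.hy926 on the log2 scale, was 3.87 for DDX31, 3.84 for RAD54L, 3.66 for EPX, 3.55 for GTF3C5 and 3.48 for RNFT2. It was -4.76 for RHOB, -4.61 for IGFBP7, -3.91 for RESF1, -3.88 for DEPP1 and -3.67 for CD9. The effect of mevalonate differed for 8 probe sets, by 5.69 for CXCL2, 5.30 for CXCL8, 4.44 for CXCL1, 4.43 for SELE, 2.53 for GTF2B and -3.04 for AQP6. Outside the tested probe sets, the GAPDH controls had a log2 ratio of 3' to 5' signal that was 2.78 higher with atorvastatin than without in HUVEC and 1.69 higher in EA.hy926. The EA.hy926 value rests on 1 array: it was 0.19 without atorvastatin replicate 1 and 3.19 without replicate 2. The HUVEC value was 1.87 and 3.69 without untreated replicate 1 or 2, and 2.60 and 2.96 without atorvastatin replicate 1 or 2.

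Many probe sets changed with atorvastatin in HUVEC on arrays of low 5' to 3' ratio. Of these calls 97.0% stayed past the threshold in the same direction with quantile normalization, which argues against scaling for the HUVEC calls. The EA.hy926 atorvastatin calls, of which far fewer remained with quantile normalization, were not part of this test. With the ratio as covariate a median of 96.1% of the change was left, which argues against a linear trend with the ratio, as seen within groups, as the whole cause. That trend is 1 slope per probe set over both cell types. It rests mostly on the untreated HUVEC and the EA.hy926 atorvastatin arrays, whose ratios differed most within a group, and a trend of another form was not tested. With the covariate 777 calls (36%) passed, with standard errors 1.26 times as large. Less labelled RNA on the atorvastatin arrays, whose hybridisation controls were the brightest group of each cell type, was not tested. Truncated RNA or cDNA stays open: between the 2 untreated HUVEC arrays, of different ratio, the called probe sets moved with the atorvastatin effect at a Pearson r of 0.186 across probe sets (0.0564 over those not called), between the bounds set for and against it. In EA.hy926 atorvastatin replicate 2, 60.7% of the HUVEC calls went the same way (52.1% of the others), which met the bound set against truncation as the whole cause; that bound assumed an ordinary ratio, but the array's GAPDH ratio of 0.655 was below those of the 6 EA.hy926 arrays not given atorvastatin alone, so it excludes nothing, and an effect of the drug on HUVEC, untested apart from the ratio, could also give the calls.

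Cytokine and adhesion genes were higher in HUVEC with mevalonate, alone or with atorvastatin. Against the atorvastatin arrays the 7 called members had a median rise of 4.47 (log2), which met the bound set against low values on the shared untreated arrays. The 7 members were chosen as called against those untreated arrays. The atorvastatin arrays had the drug and the lowest GAPDH ratios, which could lower these members too. Low untreated values are therefore not excluded. The untreated array of low ratio is argued against because 86.3% of the median rise was left against the other untreated array. The blood cell markers had a median change of -0.22 and the brightest of them changed by -0.61 (limma adjusted p = 0.736), which met the bound set against blood cells. None of the 7 measured markers was called in either direction, so a share of blood cells too small to move them is not excluded. A property of the mevalonate preparation other than mevalonate cannot be told apart from mevalonate, as CXCL2 rose by at least 5.97 on the HUVEC arrays given mevalonate alone and by at least 5.57 on all 4 given it, and a response of HUVEC to mevalonate itself also stays open. Untreated cells had no time given, so a difference in time from the mevalonate cultures was not tested and stays open too.

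More probe sets were called higher than lower in untreated HUVEC against EA.hy926. The share higher in HUVEC was 79.6%, 63.7% and 34.5% in the dimmest, middle and brightest of 3 equal parts of the probe sets, a difference of 45.2 points between the first and last, as less labelled RNA on the HUVEC arrays predicts. Less labelled RNA may therefore contribute to the split. With quantile normalization the share over all probe sets fell by 10.6 points, which met the bound set for scaling, but, as judged after the value was seen, that method gives every array the same distribution and so sets this balance by construction, and the share was 26.3% with scaling to the same median. Whether scaling contributes stays open, as does a difference between primary cells and the line, which was not tested.

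For the mean atorvastatin effect, the 8 arrays involved were divided in 35 ways with cell type as a term, of which 1 could not be fitted. Of the 34 others, 1 gave as many calls, the real one with 137, and the highest of the rest gave 0 by limma. The HUVEC arrays varied more, so arrays can be exchanged only within a cell type, a restriction set after the result was seen. The 18 splits with 2 arrays of each cell type on each side are too few for a share under 5%, and among them the highest other count was also 0 by limma. These counts come from a fit of the 8 arrays alone.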

How the results depend on the processing

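The fits with the 5' to 3' ratio as covariate and without HUVEC untreated replicate 2 and EA.hy926 atorvastatin replicate 1, and the difference in the mevalonate effect, were chosen after seeing the data.

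Counts stayed within 1.5 times, and shares left within the spread between replicates, except for the values given here; unless said otherwise the cause was not tested. For atorvastatin in HUVEC, 2158 calls became 564 within the cell type, 1034 with array weights, 844 with the covariate and 1242 without the 2 arrays. For both compounds against atorvastatin in HUVEC, 2741 became 1005 within the cell type, 1144 with weights and 146 with the covariate. For mevalonate in HUVEC, 40 became 25 with no filter, 4 within the cell type, 19 with weights and 15 with the covariate. For both compounds against untreated HUVEC, 32 became 18 with the filter at the 60th percentile, 3 within the cell type, 9 with weights, 13 with the covariate and 9 without the 2 arrays. For atorvastatin in EA.hy926, 259 became 68 with quantile normalization, 136 with no filter, 584 within the cell type, 799 with weights, 34 with the covariate and 29 without the 2 arrays. In the same order the 319 calls for both compounds against atorvastatin in EA.hy926 became 77, 142, 766, 999, 14 and 32. The 528 calls for the difference in the atorvastatin effect became 194 with no filter, 809 with trend and robust estimation and 109 without the 2 arrays. The 1537 calls of the mean effect became 98 with the covariate and 526 without the 2 arrays. The 8 calls for the difference in the mevalonate effect became 3 with the smaller pseudocount, 2 with no filter, 5 with the 60th percentile, 5 with trend, 4 with the covariate and 1 without the 2 arrays. For mevalonate and for both compounds against untreated EA.hy926, limma called 0 under every alternative that kept all arrays or left out the 2, with 117 and 144 at an unadjusted p under 0.05 as reported. The 75 calls shared by the cell types became 26 with quantile normalization, 31 with no filter, 122 with the 60th percentile, 47 within the cell types, 124 with trend, 14 with the covariate and 14 without the 2 arrays. The number that independent lists would share moved too, from 21.7 to 1.32 with the covariate. With the covariate the median share of the change left over the calls of a comparison lay between 87.5% and 102%, and standard errors were 1.01 to 1.62 times as large.

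The share of the EA.hy926 atorvastatin change left with mevalonate, 1.11%, became 2.60% with quantile normalization, 0.214% with the larger pseudocount, 2.00% with no filter, -0.498% with the 60th percentile, 0.00908% with trend, 2.52% with the replicate block and 3.57% with the covariate. The called lists became 0 from 7 (HUVEC atorvastatin), 0 from 9 (HUVEC both against atorvastatin), 2 from 4 (HUVEC both against untreated), 6 from 10 (EA.hy926 atorvastatin), 0 from 7 (difference in the atorvastatin effect) and 0 from 5 (HUVEC against EA.hy926) with an estimated correlation in camera. With fry, which asks another question, they were 19 (HUVEC atorvastatin), 22 (HUVEC both against atorvastatin), 15 (EA.hy926 both against atorvastatin, from 7), 20 (HUVEC against EA.hy926) and 13 (mean effect, from 7). With quantile normalization the difference in the atorvastatin effect had 2.

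The replicate numbers do not pair the samples consistently: deviations of same-numbered arrays correlated at -0.21 to 0.04 in HUVEC (0 of 6 pairs over 0.1) and -0.32 to 0.32 in EA.hy926 (2 of 6). A pairing of the arrays under other numbers was not tested. With the number as a replicate block the counts that moved were 9 (HUVEC both against untreated), 113 (EA.hy926 atorvastatin), 128 (EA.hy926 both against atorvastatin), 217 (difference in the atorvastatin effect), 1 (difference in the mevalonate effect) and 32 (shared calls). Atorvastatin in HUVEC gave 1735 with the block.

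Without single arrays, where a lone array is assumed to vary like the other groups, the counts ranged from 1085 to 2334 for atorvastatin in HUVEC, 1397 to 2882 for both compounds against atorvastatin, 24 to 58 for mevalonate and 15 to 88 for both against untreated. In EA.hy926 they ranged from 27 to 301, 21 to 379, 0 to 1 and 0 to 1 in that order. They ranged from 40 to 605 for the difference in the atorvastatin effect, 3923 to 6405 for HUVEC against EA.hy926, 663 to 1690 for the mean effect, 0 to 12 for the difference in the mevalonate effect and 11 to 73 for shared calls. The share left ranged from -3.26% to 15.0% in HUVEC and -1.06% to 8.15% in EA.hy926. Of 15246 values of named genes under the alternatives, 2089 no longer passed, 7 newly passed, 0 reversed and 13150 did neither. A block for the scan or hybridisation batch was not run, as the files used here gave none. Without detection calls the signal over background is unknown, which limits dim probe sets.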

Other observations

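The 2 tests of this part were written before their results were seen, and a planned test of probe sets of one gene that disagree was not run. The genes belong to lists fixed in advance, and those described here were chosen after their values were seen.

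In HUVEC, genes of lists that were not called as a whole also changed with atorvastatin. The antiviral enzyme OAS1 rose by 2.27 ± 0.36 (log2 ± SE, limma adjusted p = 0.00186, n = 2 per group), the metalloproteinase inhibitor TIMP2 by 2.18 ± 0.29 and the apelin receptor APLNR by 2.19 ± 0.34. Lower were the chaperone of the endoplasmic reticulum HSPA5 (-2.46 ± 0.37), the growth factor BMP6 (-1.89 ± 0.26), ID3, a target of BMP signalling, (-1.96 ± 0.39) and the endothelial receptor TIE1 (-2.24 ± 0.46). The low 5' to 3' ratio of the same arrays applies to these values too.

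Between untreated HUVEC and EA.hy926, where limma called 6109 of 13276 probe sets, single genes of the lists differed. The direction and call of the 7 genes given here held with quantile normalization and with scaling to the same median, although these took the share of all calls higher in HUVEC from 60.3% to 49.7% and 26.3%. The basement membrane collagen COL4A1 (3.07 ± 0.34), the proteoglycan BGN (3.85 ± 0.38), the adhesion molecule VCAM1 (2.76 ± 0.37) and the cytokine IL1B (2.88 ± 0.43) were higher in HUVEC, and PCNA (-2.01 ± 0.23) was lower. Of the blood cell markers, HBB (1.65 ± 0.30) and FCER1G (2.42 ± 0.38) were higher in HUVEC.

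The cholesterol synthesis list had a median of -0.23 over 15 members with atorvastatin in HUVEC. One hypothesis was that its members fall where the 5' to 3' ratio is low. Between the untreated HUVEC arrays of lower and higher ratio the median difference of the list was 0.37, which met the bound set against the hypothesis. The test is left open because it rests on 1 pair of arrays, a judgement made after its value was seen, so whether the ratio lowers these genes cannot be told apart from an effect of the drug.

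The KLF2 and flow response list rose with atorvastatin in EA.hy926, and 1 of the 2 arrays had a low GAPDH ratio. The hypothesis that the rise rests on that array was tested in the other array alone, where the median of the list was 1.15 against 1.16 over both, 99.3% of it. This argues against the hypothesis, while the GAPDH ratio of the other array, 0.655, was itself below those of the 6 EA.hy926 arrays not given atorvastatin alone.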
